A study of Mus musculus with 9 samples.

How the data were processed

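RNA from the quadriceps muscle of 9 male mice aged 18 months was sequenced, 1 library per mouse. Per the labels, the mice had been injected in the tail vein at 9 months of age, and the muscle was taken 9 months later. The 3 groups of 3 mice were wild-type mice given PBS (WT_PBS), Gaa knockout mice given PBS (KO_PBS) and Gaa knockout mice given the vector AAV8-sp7-delta8-hGAAco, which carries a secreted form of human acid alpha-glucosidase (KO_secGAA). Per the labels' protocols, polyadenylated RNA was prepared with Trizol and columns, libraries were made with the NEBNext Ultra RNA kit, and single-end reads of 61 bp came from a HiSeq2500. The submitters' processing notes name CASAVA, cutadapt, RSEM, limma, edgeR and the build GRCm38; which tool did which step, and their versions, are not given in the sources used here. Whether the counting used strand is not given either.

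The deposited table holds a normalized signal, named as normalized counts per the file headers, for 13116 genes in 9 columns. In every column each value divided by the smallest value was an odd whole number, within a relative tolerance of 1e-06, for 100% of the 118044 values. Whole reads could therefore be recovered: each value is the reads of a gene plus 0.5, divided by an effective library size and multiplied by 1e6. The effective size equals the library's total reads times a TMM scaling factor, since edgeR's TMM factors computed from the recovered reads gave the deposited signal back with a largest relative difference of 5.1e-15. The columns therefore do not sum to 1e6 as plain CPM would: those of KO_PBS sum to less and those of WT_PBS to more. Genes with low values had been removed before the table was deposited: all 13116 genes have at least 1 CPM, by the total reads, in at least 3 libraries. Of the gene identifiers, 83 have no symbol, and 7 symbols stand on 2 identifiers, for which the one with the higher mean was used in the gene lists. Coordinates were matched by identifier in the GENCODE M21 annotation of GRCm38 for 13077 of the 13089 genes tested.

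The plan fixed before the data were examined was to use edgeR on a table of raw counts and limma on log2 values otherwise. The table holds normalized values, so limma 3.58.1 in R 4.3.3 was used on log2(value + 0.5), with group means, no covariate, empirical Bayes moderation with a trend, and 6 residual degrees of freedom. Genes at 1 or more in at least 3 libraries were tested, which removed 27 of the 13116. The 3 comparisons were KO_PBS against WT_PBS, KO_secGAA against KO_PBS and KO_secGAA against WT_PBS. A gene is said to have risen, fallen or changed where the Benjamini-Hochberg adjusted p of limma was under 0.05. All log2 fold changes and the folds made from them are on the log2(value + 0.5) scale, which shrinks those of genes at low values. Every adjusted p of a gene in the text comes from this fit unless another tool is named. Group values are the mean ± SD of the normalized signal of 3 mice, called normalized counts below.

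Gene lists were also fixed in advance: 21 for muscle, metabolism, lysosomal storage, stress and immune functions, 2 for signs of handling (circadian clock and immediate early genes), and 12 of cell type markers. They hold 729 genes, of which 673 were tested; 19 are in more than 1 list. Every one of the 35 lists had at least 5 tested members. Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists, and again with the correlation estimated from the data; fry was the other list test. Camera compares a list with all other genes, and fry asks whether its genes move on balance one way. Counts given as adjusted over the list alone take only the p-values of that list's genes. The markers describe transcripts of bulk tissue, not numbers of cells.

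The genes named were chosen by rule. They are Gaa; the 8 largest rises and 8 largest falls of each comparison among changed genes whose groups did not overlap and whose higher group mean was at 5 or more, without predicted genes; up to 4 members of each list that passed, by smallest p in the list's direction; and up to 2 members of each marker or handling list that did not pass. Genes named in 1 comparison were given again in the others where useful. Genes named outside the rule are marked as chosen after their values were seen.

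Genes called in 2 comparisons that share the KO_PBS libraries were counted beside 100 simulated sets of unchanged groups and beside the overlap that independent lists would give. In a further check, genes were called with 1 KO_PBS and 1 WT_PBS library left out, and the mean of the treated libraries was compared with the left-out KO_PBS and WT_PBS libraries. The test was tried on simulated reads with the real libraries' means and sizes over 12886 genes. For KO_PBS against WT_PBS it recovered 52% of the genes changed 2-fold and 8.16% of those changed 1.5-fold, with 10.45% of calls false. For KO_secGAA against KO_PBS the shares were 48%, 10% and 6.45%, and for KO_secGAA against WT_PBS 40%, 4.17% and 12%. In KO_PBS against WT_PBS they rest on 100 and 98 changed genes and on 7 false calls of 67. Shares can differ where many more genes change, as in the real comparison. In the list test, the list that had been changed was called and 0 of 35 unchanged lists were, each simulated for KO_PBS against WT_PBS. The simulated genes varied independently. This trial therefore does not cover false calls of lists whose genes vary together, such as oxidative phosphorylation with an estimated correlation of 0.844.

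The alternatives tried were pseudocounts of 1 and 0.1, no filter, a filter at 5, values rescaled by TMM or median-of-ratios factors, quantile normalization, a fit of the 2 compared groups only, moderation without trend or with robust settings, array weights, each library left out in turn, a minimum of 1.5-fold, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads and, chosen after the data were seen, values without scaling factors, limma voom, and reads thinned to the smallest library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out. Replicates of different groups share only a number given in the order of the samples, so no paired fit was made.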

Results

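The study measured messenger RNA in quadriceps muscle of mice lacking acid alpha-glucosidase (Gaa), the lysosomal enzyme that breaks down glycogen and whose loss causes Pompe disease. Its 9 libraries came from 3 mice per group: wild-type mice given PBS (WT_PBS), knockout mice given PBS (KO_PBS) and knockout mice given a liver-directed vector for a secreted human enzyme (KO_secGAA). Reads in the genes of the table numbered 15957106, 15831264 and 15477523 in WT_PBS, 14355201, 11437512 and 9299156 in KO_PBS and 10495715, 11323672 and 14406655 in KO_secGAA. A single read stood for 0.0652 to 0.0922 normalized counts, so 3 reads, the least that is distinguished here from 0, were 0.196 to 0.276. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.969 to 0.986 for the 9 pairs of libraries within a group and 0.936 to 0.972 for the 27 pairs between groups. The first principal component held 40.6% of the variance. On it WT_PBS lay at -40.59 to -33.76, KO_PBS at 23.77 to 37.30 and KO_secGAA between them at -1.36 to 10.79.

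Gaa (ENSMUSG00000025579), the targeted gene, lies on chromosome 11 at 119267887 to 119285454 (GRCm38). Its normalized counts were 296, 128.6 and 264.1 in the WT_PBS mice, 17.78, 14.46 and 14.02 in the KO_PBS mice and 15.07, 15.6 and 16.61 in the KO_secGAA mice. The means were 229.6 ± 88.9, 15.42 ± 2.05 and 15.76 ± 0.783 (SD, n = 3). Gaa fell by 3.77 on the log2 scale in KO_PBS against WT_PBS (SE 0.26, limma adjusted p = 3.1e-05) and by 3.74 in KO_secGAA against WT_PBS (adjusted p = 0.000204). KO_secGAA and KO_PBS differed by 0.04 (SE 0.26, adjusted p = 0.959), with the sign depending on which library was left out (-0.025 without KO_PBS 3, 0.141 without KO_PBS 1) and on the scaling (-0.112 without scaling factors). Every wild-type library was above every knockout library. Whether reads of the human transgene could map to the mouse gene was not examined.

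KO_PBS against WT_PBS asked what loss of the enzyme changed in muscle. Risen genes included 13 of 19 for muscle regeneration, 15 of 27 for denervation, 21 of 63 for lysosomes and 13 of 27 macrophage markers, and fallen genes 9 of 14 for fast fibres, 10 of 21 for glycolysis and 17 of 53 for oxidative phosphorylation. Of the 21 lists called, only regeneration held with an estimated correlation (adjusted p = 0.0256). Among the largest rises were Mt3, a metallothionein that binds zinc and copper, from 1.493 ± 0.301 to 113.2 ± 36.1 normalized counts, and Ahnak2, from 6.317 ± 1.33 to 257.3 ± 28.5. Among the largest falls was Mstn, the gene of myostatin that limits muscle growth, from 50.08 ± 13.2 to 3.732 ± 1.44. The macrophage gene Lgals3, a galectin that binds damaged lysosomes, rose from 7.365 ± 1.02 to 79.92 ± 13.1.

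The log2 fold changes of these genes were 5.80 for Mt3 (SE 0.27, adjusted p = 5.4e-06), 5.25 for Ahnak2 (SE 0.28, adjusted p = 8.5e-06), -3.60 for Mstn (SE 0.28, adjusted p = 5.2e-05) and 3.35 for Lgals3 (SE 0.25, adjusted p = 4.6e-05). Mt3 lies on chromosome 8 at 94152607 to 94154146, Ahnak2 on chromosome 12 at 112772194 to 112802657, Mstn on chromosome 1 at 53061640 to 53068079 and Lgals3 on chromosome 14 at 47367751 to 47386160. Fetub, of the fetuin family, went from 0.271 ± 0.212 to 15.83 ± 0.747 normalized counts, and Kcnn4, a calcium-activated potassium channel, from 0.413 ± 0.030 to 12.70 ± 5.43. Kcnab1, a subunit of voltage-gated potassium channels, fell by 4.43 on the log2 scale, and Dkk3 went from 26.11 ± 16.5 to 1.175 ± 0.198. The potassium channel gene Kcnf1 fell by 3.25, the lysine methyltransferase gene Mettl21c by 3.19 and Aqp4, a water channel of fast fibres, by 3.15. Odf3l2 fell too (adjusted p = 0.00225), with WT_PBS mice at 125.4, 7.834 and 42.75 and KO_PBS at 0.388 ± 0.321, but did not pass with limma voom.

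**Figure D1:**
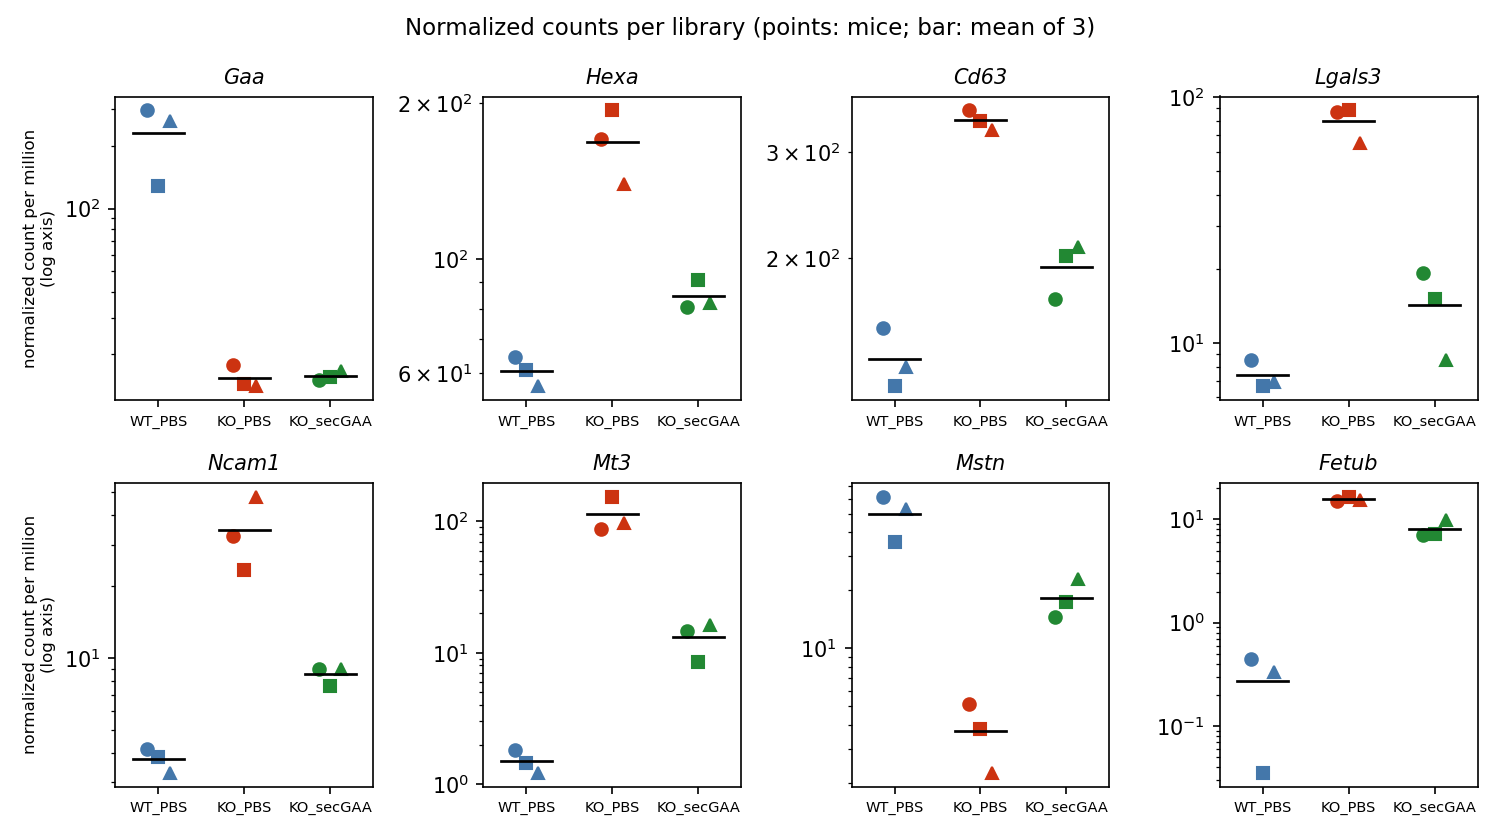
Normalized counts (log axis) of 8 named genes in each of the 9 libraries; points are mice (circle, square and triangle for replicates 1, 2 and 3) and bars are means of 3. Gaa lay near 15 in all 6 knockout libraries, and the other 7 genes had KO_secGAA means between those of the other groups.

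Among genes of lysosomal storage and sugar use, 21 of 63 lysosomal genes rose, 0 fell and 42 did not pass (24 rose and 1 fell adjusted over the list alone). Cd63, a membrane protein of lysosomes, rose by 1.32 on the log2 scale, Hexa, a subunit of beta-hexosaminidase, 2.73-fold, and the proteases Lgmn 2.37-fold and Ctsl 2.76-fold. Camera gave the list an adjusted p = 5.1e-07 (adjusted p = 0.313 with an estimated correlation). Cd63, Lgmn and Ctsl are also abundant in macrophages, whose marker list had a median of 0.99 in the same comparison, against 0.33 for the lysosomal list. Of 16 subunits and partners of the proton pump that acidifies lysosomes, 5 rose and 1 fell (7 and 1 adjusted over the list alone). Atp6v1h rose 2.67-fold, Atp6ap2 2.43-fold and Atp6v1a 2.19-fold (list adjusted p = 0.00269; adjusted p = 0.502 with an estimated correlation). Atp6v0d1 rose 1.44-fold, a call that ended without WT_PBS 2, KO_PBS 1 or KO_PBS 2 (adjusted p up to 0.0678). Of 35 autophagy genes, 6 rose and 5 fell (the same adjusted over the list alone), and the list did not pass (adjusted p = 0.793). Of 21 genes of glycogen metabolism, 2 rose and 7 fell (3 and 9 adjusted over the list alone). The falls included the phosphorylase kinase subunits Phkg1, by 1.13 on the log2 scale, and Phkb, by 0.95, and the muscle glycogen phosphorylase Pygm, by 0.95. That list passed narrowly (adjusted p = 0.0456; adjusted p = 0.502 with an estimated correlation) and not without WT_PBS 1, WT_PBS 3, KO_PBS 2, KO_PBS 3 or KO_secGAA 1 (adjusted p up to 0.119).

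Among genes of energy metabolism, of 21 glycolysis genes, 10 fell and 2 rose (11 and 2 adjusted over the list alone). Pfkfb1 fell by 1.70 on the log2 scale and the phosphoglycerate mutase of muscle, Pgam2, by 0.99 (list adjusted p = 0.000835; adjusted p = 0.502 with an estimated correlation). Of 53 genes of oxidative phosphorylation encoded in the nucleus, 17 fell, 0 rose and 36 did not pass (17 adjusted over the list alone). The list had an adjusted p = 1.1e-07 (adjusted p = 0.653 with an estimated correlation). Of 18 genes of the TCA cycle, 11 fell and 1 rose (15 and 1 adjusted over the list alone). Suclg1 was lower by 0.68 and the citrate synthase Cs, which did not pass without scaling factors, by 0.55 (list adjusted p = 1.5e-05; adjusted p = 0.544 with an estimated correlation). Of 21 genes of fatty acid oxidation, 2 fell (0 adjusted over the list alone), Acadm and Cpt1b, by 0.61 and 0.36 (list adjusted p = 0.0176; adjusted p = 0.741 with an estimated correlation). Both calls ended without WT_PBS 2, WT_PBS 3, KO_PBS 2 or KO_PBS 3 (adjusted p up to 0.0769 for Acadm and 0.133 for Cpt1b), and that of the list without WT_PBS 2 or KO_PBS 3 (adjusted p up to 0.291). WT_PBS 1 stood apart from its group, so the groups overlapped: its averages of the oxidative phosphorylation, TCA cycle and fatty acid lists were -0.277, -0.233 and -0.279, against -0.174, -0.184 and -0.019 in KO_PBS 1 and -0.228 for fatty acids in KO_PBS 2. These falls are relative to the median gene. Without the authors' scaling factors, where the median of all genes shifted by 0.305, the medians of the oxidative phosphorylation and glycogen lists were both -0.01. That of the fatty acid list turned to 0.10, with its call lost (adjusted p = 0.0891). Mitochondrially encoded genes took 14.4 ± 2.71% of reads in WT_PBS, 10.2 ± 0.405% in KO_PBS and 11.7 ± 0.398% in KO_secGAA.

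Muscle fibre genes changed in several directions. Of 19 genes of muscle regeneration, 13 rose, 0 fell and 6 did not pass (15 adjusted over the list alone). Ncam1, an adhesion molecule of developing and denervated fibres, rose 7.96-fold, the embryonic light chain Myl4 9.36-fold, the intermediate filament Nes 4.15-fold and the transcription factor Runx1 4.47-fold. The list had an adjusted p = 4.6e-08, and adjusted p = 0.0256 with an estimated correlation. Of 27 genes of denervation and atrophy, 15 rose and 0 fell (16 adjusted over the list alone). Sln, an inhibitor of the sarcoplasmic calcium pump, rose 13.3-fold and the stress gene Gadd45a 4.54-fold (list adjusted p = 1.1e-07; adjusted p = 0.0734 with an estimated correlation). Of 10 slow fibre genes, 7 rose (9 adjusted over the list alone). Casq2, the slow and cardiac calsequestrin, rose 3.25-fold and Atp2a2, the slow and cardiac calcium pump, 4.66-fold (list adjusted p = 0.00011; adjusted p = 0.502 with an estimated correlation). The slow myosin Myh7 rose as well (adjusted p = 0.0143), but not without WT_PBS 3 (adjusted p = 0.0588). Its mice differed widely, at 0.6513, 32.92 and 1.221 in WT_PBS and 656.3, 101.3 and 116.3 in KO_PBS. The slow fibre list averages also varied widely within WT_PBS, at -1.614, 1.677 and -0.063, against 4.151, 2.627 and 2.137 in KO_PBS. Tnnt1 and Tnnc1, slow troponins, rose by 3.72 and 4.07 on the log2 scale, calls that ended without WT_PBS 1, WT_PBS 3, KO_PBS 1 or KO_PBS 2 (adjusted p up to 0.0758 and 0.085). Of 14 fast fibre genes, 9 fell (11 adjusted over the list alone). The fast calsequestrin Casq1 was lower by 1.06 and the fast troponin Tnnc2 by 0.79 (list adjusted p = 7.7e-05; adjusted p = 0.502 with an estimated correlation). With quantile normalization, which sets the values of the most abundant genes alike, Tnnc2 was lower by only 0.052 and no longer passed, nor did the glycolysis gene Tpi1.

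Among immune, matrix and stress genes, of 27 macrophage markers, 13 rose and 0 fell (20 adjusted over the list alone). Cd68, a lysosomal membrane protein of macrophages, rose 3.84-fold and the pore-forming Mpeg1 4.36-fold (list adjusted p = 5.2e-08; adjusted p = 0.502 with an estimated correlation). Of 16 genes of antigen presentation, 8 rose (8 adjusted over the list alone). The class II genes H2-Eb1 and H2-Aa rose 3.30-fold and 3.41-fold and the invariant chain Cd74 3.07-fold (list adjusted p = 0.000157; adjusted p = 0.653 with an estimated correlation). These class II transcripts are typical of macrophages and other presenting cells. KO_PBS 1 stood lower than its group, with a list average of 0.350 log2 units above WT_PBS against 1.025 and 1.201. Of 24 interferon response genes, 5 rose (6 adjusted over the list alone), such as Isg15, 3.21-fold, and Irgm1, 1.71-fold (list adjusted p = 0.000771; adjusted p = 0.653 with an estimated correlation). Of 15 complement genes, C3ar1, a receptor, rose 2.37-fold (1 adjusted over the list alone; list adjusted p = 0.0456; adjusted p = 0.741 with an estimated correlation). The list's call ended without WT_PBS 3, KO_PBS 2, KO_PBS 3 or KO_secGAA 1 (adjusted p up to 0.305), and WT_PBS 1, at 0.442, lay among the KO_PBS mice (0.254 to 0.443). Of 36 matrix genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone). The groups overlapped, with the matrix average of KO_PBS 1, 0.09, below that of WT_PBS 2, 0.131. Timp1, an inhibitor of matrix proteases, rose 8.62-fold, the proteoglycan Lum 2.94-fold and the gelatinase Mmp2 1.60-fold (list adjusted p = 0.00569; adjusted p = 0.653 with an estimated correlation; adjusted p = 0.125 without KO_PBS 2). Without scaling factors the interferon, complement and matrix lists did not pass (adjusted p = 0.0625, 0.372 and 0.136). Of 24 oxidative stress genes, 12 rose and 1 fell (14 and 1 adjusted over the list alone). Thioredoxin, Txn1, rose 2.23-fold and the quinone reductase Nqo1 3.09-fold (list adjusted p = 3.6e-06; adjusted p = 0.502 with an estimated correlation). Of 20 genes of the unfolded protein response, 9 rose (9 adjusted over the list alone). The chaperone Canx rose 1.73-fold, the pseudokinase Trib3 10.5-fold and asparagine synthetase, Asns, 6.70-fold (list adjusted p = 7.7e-05; adjusted p = 0.502 with an estimated correlation). Of 42 ribosomal protein genes, 8 rose (4 adjusted over the list alone), with Rpl3 at 1.85-fold (list adjusted p = 3.1e-05; adjusted p = 0.653 with an estimated correlation). Reads of these genes can be shared with processed pseudogenes.

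Of 12 endothelial markers, 5 fell (5 adjusted over the list alone), with Esam lower by 0.56 on the log2 scale (list adjusted p = 0.00429; adjusted p = 0.502 with an estimated correlation). Without scaling factors Esam did not pass (adjusted p = 0.141), though the list did. The erythroid list passed as lower (adjusted p = 0.0456; adjusted p = 0.653 with an estimated correlation) although 0 of its 5 tested genes passed in limma, edgeR or DESeq2 and 3 had an unadjusted p under 0.05. Hbb-bs was at 141.6 ± 60.7 and 48.81 ± 32.4. The list's call ended without WT_PBS 1, WT_PBS 3 or KO_PBS 2 (adjusted p up to 0.148). Lists that did not pass were proteasome (median log2 fold change 0.06, adjusted p = 0.0735), proliferation (0.35, 0.708), T and NK cells (-0.46, 0.89), B and plasma cells (1.09, 0.71), neutrophils and mast cells (0.07, 0.898), fibroblasts (0.03, 0.27), adipocytes (-0.84, 0.115). Neither did smooth muscle and pericytes (-0.08, 0.51), Schwann cells (0.03, 0.793), satellite cells (0.36, 0.114) and tendon and cartilage (-0.17, 0.898, with a test direction opposite to the median). Without scaling factors the proteasome list passed as higher (median 0.38, adjusted p = 3.7e-06) and the adipocyte list as lower (adjusted p = 0.00373). Among their members, Ccl5 of T cells rose from 0.2532 ± 0.201 to 1.844 ± 0.331 and the pericyte gene Rgs5 fell by 0.54, though not without scaling factors, while Adipoq of fat cells lay at 38.3 ± 34.9 and 17.18 ± 7.50. Other members went the opposite way: Thy1 of T cells fell by 0.74, Cspg4 of pericytes rose 2.33-fold and Ighm of the B cell list fell 8.69-fold. Each call ended without WT_PBS 3 or KO_PBS 2, those of Thy1 and Ighm also without KO_PBS 1, that of Thy1 without WT_PBS 2 and that of Ighm without WT_PBS 1 (adjusted p up to 0.0907, 0.0957 and 0.0738 for Thy1, Cspg4 and Ighm). Thy1 did not pass without scaling factors either, nor Ighm with edgeR. Reads of the antibody light chain Igkc were at most 0.818% of those of Ighm in WT_PBS, so B cells are not a likely source of Ighm there. The handling lists did not pass either (clock -0.12, adjusted p = 0.898; immediate early -0.26, adjusted p = 0.898, with a mean of 0.11 and a test direction opposite to the median), although Junb rose 3.29-fold and Hlf fell by 1.14. Of 18 immediate early genes, 5 rose and 1 fell (5 and 3 adjusted over the list alone), against 21.9% changed of all genes. KO_PBS 3 stood apart in this sign of handling, with an average of -0.727 against 0.482 and 0.581.

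In limma, 2867 of 13089 genes changed, 1430 up and 1437 down, and 859 of them by at least 2-fold (570 up, 289 down). The groups did not overlap for 39.7% of genes, where chance gives 10%. Without scaling factors 4985 genes passed, of which 89.6% were up in place of 49.9%. The count was 1744 without WT_PBS 3 and 1844 without KO_PBS 2, and with an estimated correlation 1 of the 21 called lists (13 up, 8 down) held, while fry called 14.

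**Figure D2:**
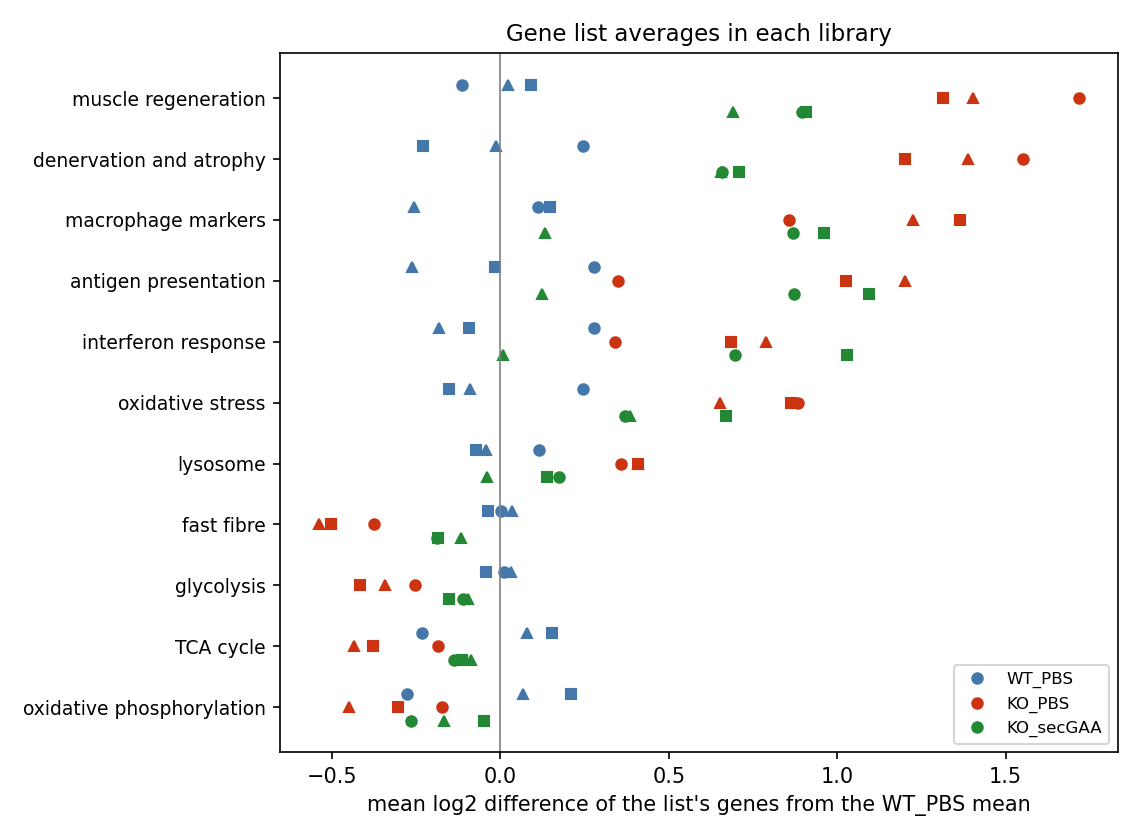
Mean log2 difference from the WT_PBS mean over the tested genes of 11 lists, in each of the 9 libraries (circle, square and triangle for replicates 1, 2 and 3). KO_secGAA 3 lay nearer to WT_PBS than the other treated mice for macrophage markers, antigen presentation and interferon response.

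KO_secGAA against KO_PBS asked what treatment with the vector of the secreted enzyme changed in knockout muscle. No group was given a vector without the enzyme, so effects of the vector and of the enzyme cannot be told apart. Several genes that had risen with the knockout came down, in part: Mt3 went from 113.2 ± 36.1 to 13.10 ± 4.12 normalized counts, Lgals3 from 79.92 ± 13.1 to 14.31 ± 5.42, and Ahnak2 from 257.3 ± 28.5 to 49.52 ± 24.1. Mstn went up from 3.732 ± 1.44 to 18.33 ± 4.29, and Mettl21c from 5.788 ± 3.26 to 26.40 ± 4.55. Of the lists, 7 of 63 lysosomal, 4 of 19 regeneration and 4 of 27 denervation genes fell. With an estimated correlation 0 of the 18 lists called in this comparison held (adjusted p from 0.0689 for regeneration to 0.762 for oxidative phosphorylation).

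Among the largest falls were Mt3, by 3.07 on the log2 scale (SE 0.27, adjusted p = 0.000963), Anxa8, an annexin, by 2.86, Card14, an adaptor of NF-kB signalling, by 2.61, Kcnn4 by 2.58 and Ahnak2 by 2.46. Lgals3 fell 5.66-fold (adjusted p = 0.00229), and the acetylcholine receptor subunit Chrnd fell by 2.43 and Mdfi, an inhibitor of myogenic transcription factors, by 2.26. Among the largest rises were Mettl21c, 4.60-fold, Mstn, 4.56-fold (SE 0.28 on the log2 scale, adjusted p = 0.00497), Mettl11b, 3.69-fold, the processed pseudogene BC023105, 3.28-fold, and Ybx2, an RNA-binding protein, 2.78-fold. Lep, the gene of the fat hormone leptin, rose 10.5-fold, from 1.357 ± 1.16 to 18.69 ± 12.6, and its call ended without KO_secGAA 2 (adjusted p = 0.0678). Dkk3 and Gdap1 rose 3.42-fold and 3.09-fold, and both calls ended without any 1 of the KO_secGAA libraries (adjusted p up to 0.101 and 0.0642). That of Dkk3 also ended without WT_PBS 3 or any 1 of the KO_PBS libraries.

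Of 63 lysosomal genes, 7 fell, 0 rose and 56 did not pass (16 fell adjusted over the list alone). Hexa fell by 0.97 on the log2 scale, Lgmn by 0.88, Cd63 by 0.81 and the membrane protein Lamp1 by 0.60, the last not without KO_secGAA 2 (adjusted p = 0.0544). The list had an adjusted p = 1.8e-09 (adjusted p = 0.14 with an estimated correlation). Its median was -0.27 (-0.31 to -0.21 with 1 library left out) and that of the macrophage markers -0.41 (-0.63 to -0.12). Among treated mice both list averages were lowest in KO_secGAA 3 (-0.04 and 0.133 log2 units from WT_PBS). Of 16 proton pump genes, 3 fell (1 rose and 3 fell adjusted over the list alone), Atp6v1a, Atp6v1h and Atp6ap2, by 0.74, 0.53 and 0.49 (list adjusted p = 0.00152; adjusted p = 0.598 with an estimated correlation). Each of the 3 calls ended without KO_PBS 1, KO_PBS 2 or KO_secGAA 1. That of Atp6v1a also ended without KO_PBS 3 or KO_secGAA 2, that of Atp6v1h without WT_PBS 2, WT_PBS 3 or KO_secGAA 3, and that of Atp6ap2 without any of the last 3 or KO_secGAA 2 (adjusted p up to 0.0906, 0.121 and 0.142). Of 21 glycogen genes, Phkg1 and Phkb rose, 1.76-fold and 1.67-fold (6 up and 1 down adjusted over the list alone; list adjusted p = 0.00593; adjusted p = 0.598 with an estimated correlation). Phkb did not pass without KO_PBS 2 (adjusted p = 0.0508). Of 21 glycolysis genes, 3 rose and 1 fell (9 and 2 adjusted over the list alone), with Pfkfb1 at 2.57-fold (list adjusted p = 0.00222; adjusted p = 0.641 with an estimated correlation). Tpi1 and Pgam2, at 1.44-fold and 1.48-fold, did not pass without WT_PBS 3, KO_PBS 2, KO_PBS 3, KO_secGAA 2 or KO_secGAA 3. Nor did Tpi1 without KO_PBS 1, or Pgam2 without WT_PBS 2 or KO_secGAA 1 (adjusted p up to 0.101 and 0.126).

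The mitochondrial lists passed as higher without changed genes. In limma, 0 of 53 oxidative phosphorylation genes, 0 of 18 TCA cycle genes and 0 of 21 fatty acid genes changed, against 8, 9 and 2 higher at an unadjusted p under 0.05, 0 in each list with edgeR and 2, 4 and 1 with DESeq2. Adjusted over the list alone, 4 TCA cycle genes rose and 0 of the other lists. The list medians were 0.17, 0.27 and 0.19 (adjusted p = 0.000184, 7.2e-05 and 0.00222; adjusted p = 0.762, 0.663 and 0.742 with an estimated correlation). With 1 library left out, the medians of the first and last were 0.11 to 0.24 and 0.08 to 0.27. Their groups overlapped, with KO_PBS 1 at -0.174 and -0.019 against -0.266 in KO_secGAA 1 and -0.069 in KO_secGAA 3. Without KO_PBS 3 the first and last did not pass (adjusted p = 0.0539 and 0.0958). Without scaling factors, which lowered the median of all genes to -0.144, these medians were 0.02, 0.12 and 0.04. Of 14 fast fibre genes, Casq1 rose 1.57-fold (2 adjusted over the list alone; list adjusted p = 0.000173; adjusted p = 0.598 with an estimated correlation), and its call ended without WT_PBS 3, KO_PBS 1, KO_PBS 2 or any 1 of the KO_secGAA libraries (adjusted p up to 0.0844) and without scaling factors. The slow fibre list passed as lower (median -0.87, or -1.28 to -0.41 with 1 library left out, adjusted p = 0.0318; adjusted p = 0.742 with an estimated correlation), with 0 of 10 genes changed in limma, edgeR or DESeq2, 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone. That call ended without KO_PBS 1, KO_secGAA 1 or KO_secGAA 2 (adjusted p up to 0.322) and without scaling factors (adjusted p = 0.248). The groups overlapped, with slow fibre averages of 4.151, 2.627 and 2.137 in KO_PBS and 2.1, 0.931 and 2.986 in KO_secGAA.

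Of 19 regeneration genes, 4 fell (9 adjusted over the list alone). They were Ncam1, lower by 1.91 on the log2 scale, the cardiac actin Actc1, by 1.48, Nes by 1.40 and the satellite cell cadherin Cdh15 by 0.59 (list adjusted p = 6.4e-06; adjusted p = 0.0689 with an estimated correlation). The call of Cdh15 ended without any 1 of the KO_PBS libraries, KO_secGAA 1 or KO_secGAA 2 (adjusted p up to 0.0852). Of 27 denervation genes, 4 fell (10 adjusted over the list alone), with the acetylcholine receptor genes Chrnd and Chrna1 lower by 2.43 and 1.46 (list adjusted p = 4.9e-06; adjusted p = 0.12 with an estimated correlation). Sln, lower by 1.43, did not pass without WT_PBS 2, WT_PBS 3, KO_PBS 1, KO_PBS 2, KO_secGAA 2 or KO_secGAA 3 (adjusted p up to 0.131). Of 36 matrix genes, 5 fell (7 adjusted over the list alone), with Timp1 lower by 2.23, Lum by 1.23 and Mmp2 by 0.75 (list adjusted p = 9.7e-05; adjusted p = 0.663 with an estimated correlation). The median was -0.34 (-0.44 to -0.14 with 1 library left out). KO_PBS 2 had the highest matrix average, and KO_PBS 1 lay within the treated range (0.09, 0.736 and 0.377 in KO_PBS; 0.069, 0.203 and -0.191 in KO_secGAA). Of 24 oxidative stress genes, Gpx4, which reduces lipid peroxides, and Txn1 fell, by 0.60 and 0.53 (5 adjusted over the list alone; list adjusted p = 0.00798; adjusted p = 0.663 with an estimated correlation). Txn1 did not pass without KO_PBS 1, KO_secGAA 1 or KO_secGAA 3 (adjusted p up to 0.0634), nor the list without KO_secGAA 1 (adjusted p = 0.0986). The groups overlapped, with an oxidative stress average of 0.67 in KO_secGAA 2 against 0.651 in KO_PBS 3. Of 20 unfolded protein response genes, Canx fell by 0.48 (1 adjusted over the list alone; list adjusted p = 0.0235; adjusted p = 0.724 with an estimated correlation). Without KO_PBS 1 or KO_secGAA 3 neither Canx nor the list passed. Canx also did not pass without KO_PBS 2, nor the list without KO_secGAA 1 (adjusted p up to 0.0614 and 0.147). Here too the groups overlapped, with a list average of 0.652 in KO_secGAA 2 against 0.544 and 0.627 in KO_PBS 2 and KO_PBS 3.

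Of 27 macrophage markers, Lgals3 and Cd68 fell, the latter by 0.99 (3 adjusted over the list alone; list adjusted p = 0.000165; adjusted p = 0.668 with an estimated correlation). Cd68 did not pass without WT_PBS 3 or any 1 knockout library (adjusted p up to 0.14). The list averages of the treated mice were 0.869, 0.961 and 0.133 log2 units above WT_PBS, against 0.857, 1.363 and 1.226 in KO_PBS. The groups therefore overlapped: only KO_secGAA 3 lay below every KO_PBS mouse, and KO_secGAA 1 and KO_secGAA 2 lay within the KO_PBS range. Antigen presentation, complement and interferon response did not pass (adjusted p = 0.196, 0.28 and 0.679), the last with a median of 0.09 and a test direction of lower. Adipocyte markers passed as higher, with Lep changed (1 adjusted over the list alone; list adjusted p = 0.00583; adjusted p = 0.663 with an estimated correlation; adjusted p = 0.0944 without KO_PBS 3). Their median was 0.75 (0.49 to 1.08 with 1 library left out), and the rise was absent in KO_secGAA 3, with averages of 0.536, 0.735 and -0.569 in treated mice against -0.622, -0.187 and -1.188 in KO_PBS. Endothelial markers passed as higher (adjusted p = 0.00233; adjusted p = 0.641 with an estimated correlation) with 0 genes changed in limma or edgeR, 1 in DESeq2, 3 at an unadjusted p under 0.05 and 1 adjusted over the list alone. Tendon and cartilage markers passed as lower (adjusted p = 0.0235; adjusted p = 0.663 with an estimated correlation), with Scx, a transcription factor of tendon, lower by 0.95 (1 adjusted over the list alone). Scx did not pass without WT_PBS 2, KO_PBS 2, KO_PBS 3 or any 1 of the KO_secGAA libraries, nor the list without KO_PBS 1 or KO_PBS 3 (adjusted p up to 0.117 and 0.0837) or without scaling factors (adjusted p = 0.0886). The other 14 lists did not pass, at adjusted p from 0.06 (B and plasma cells) to 0.967 (T and NK cells). Without scaling factors 6 of them passed: autophagy, proteasome and ribosome as lower (adjusted p = 0.0494, 4.9e-05 and 0.000196), and immediate early genes, B and plasma cells and erythroid markers as higher (adjusted p = 0.00698, 0.00334 and 0.016).

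In limma, 481 genes changed, 179 up and 302 down, 133 of them by at least 2-fold. The groups did not overlap for 24% of genes, where chance gives 10%. The count lay between 159 and 302 when any 1 library of KO_PBS or KO_secGAA was left out, at 260 without WT_PBS 3, and at 958 without scaling factors, of which 10.6% were up in place of 37.2%. With an estimated correlation 0 of 18 called lists (8 up, 10 down) held and 3 had an unadjusted p under 0.05, while fry called 6.

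KO_secGAA against WT_PBS asked how far treated muscle still differed from wild-type. Of the largest differences, Fetub remained at 8.033 ± 1.56 normalized counts against 0.271 ± 0.212 in WT_PBS, Ctxn3, a small membrane protein, at 197.6 ± 17.6 against 31.17 ± 11.7, and Kcnk5, a pH-sensitive potassium channel, at 7.484 ± 0.711 against 0.763 ± 0.260. Scd2, a desaturase that makes monounsaturated fatty acids, was at 11.57 ± 2.59 against 72.43 ± 8.76, and Itga4, an integrin subunit, at 2.310 ± 0.375 against 12.79 ± 2.73. Higher than in WT_PBS were 4 of 19 genes of regeneration, 7 of 27 of denervation, 5 of 24 of oxidative stress and 2 of 20 of the unfolded protein response. None of these 4 lists held with an estimated correlation (adjusted p = 0.12, 0.209, 0.783 and 0.783).

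Fetub was higher by 3.49 on the log2 scale (SE 0.23, adjusted p = 0.000164), Ahnak2 by 2.79 (adjusted p = 0.00147), Mt3 by 2.73 (adjusted p = 0.00147), Ctxn3 by 2.71 (adjusted p = 0.000499) and Kcnk5 by 2.68 (adjusted p = 0.000164). Cdkn2a, an inhibitor of the cell cycle, was at 11.18 ± 7.77 against 0.3965 ± 0.371. Trib3 and Rrad, a GTPase that inhibits calcium channels, were higher by 2.86 and 2.73. The 3 calls ended without WT_PBS 3 or KO_secGAA 2 (adjusted p up to 0.124, 0.0584 and 0.0802). Those of Cdkn2a and Rrad also ended without KO_secGAA 1, and that of Cdkn2a without WT_PBS 1 or WT_PBS 2. Among the falls, Kcnab1 was lower by 2.73, Scd2 by 2.61 (SE 0.19, adjusted p = 0.000223), Tiam1, an activator of Rac, by 2.45, Itga4 by 2.23 and Efcab6 by 2.17. Cdh4 and Dkk3 fell by 2.07 and 2.03, calls that ended without WT_PBS 3, KO_secGAA 1 or KO_secGAA 2 (adjusted p up to 0.066 and 0.0774).

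Of 19 regeneration genes, 4 were higher (9 up and 1 down adjusted over the list alone), with Runx1 at 3.19-fold and Myl4 at 5.01-fold (list adjusted p = 5.2e-05; adjusted p = 0.12 with an estimated correlation). Myl4 did not pass without KO_secGAA 2 (adjusted p = 0.0522). Of 27 denervation genes, 7 were higher (11 adjusted over the list alone), with Sln at 4.94-fold and Gadd45a at 3.01-fold (list adjusted p = 5.1e-05; adjusted p = 0.209 with an estimated correlation). Of 24 oxidative stress genes, 5 were higher (10 adjusted over the list alone), with Nqo1 at 2.23-fold and Txn1 at 1.55-fold, both not without WT_PBS 3 (adjusted p = 0.0545 for each; list adjusted p = 1.7e-05; adjusted p = 0.783 with an estimated correlation). Of 20 unfolded protein response genes, Trib3 and Xbp1, a transcription factor of that response, were higher (4 adjusted over the list alone; list adjusted p = 0.000188; adjusted p = 0.783 with an estimated correlation). Xbp1, at 1.56-fold, did not pass without WT_PBS 2, WT_PBS 3, KO_secGAA 1 or KO_secGAA 2 (adjusted p up to 0.118), and Trib3 not without WT_PBS 3 or KO_secGAA 2 (adjusted p up to 0.0584). Of 42 ribosomal genes, Rps7 was higher, 2.35-fold (1 adjusted over the list alone; list adjusted p = 9.5e-05; adjusted p = 0.783 with an estimated correlation), but not without WT_PBS 3 (adjusted p = 0.0512), and its reads can be shared with processed pseudogenes. The ribosomal list had a median of 0.16 (0.09 to 0.27 with 1 library left out), and its average in KO_secGAA 1, -0.057, was at the wild-type level, against 0.302 and 0.257 in the other treated mice.

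Of 27 macrophage markers, Mpeg1 and Cd68 were higher (6 adjusted over the list alone; list adjusted p = 6.5e-06; adjusted p = 0.783 with an estimated correlation), at 2.59-fold and 1.94-fold. Neither passed without WT_PBS 3, KO_PBS 2, KO_PBS 3, KO_secGAA 1 or KO_secGAA 2, nor Mpeg1 without WT_PBS 1, nor Cd68 without WT_PBS 2, KO_PBS 1 or KO_secGAA 3 (adjusted p up to 0.134 and 0.159). Of 24 interferon response genes, Igtp was higher, 2.24-fold (1 adjusted over the list alone; list adjusted p = 5.7e-05; adjusted p = 0.783 with an estimated correlation), but not without any 1 of the WT_PBS libraries, KO_secGAA 1 or KO_secGAA 2 (adjusted p up to 0.117). The antigen presentation list was higher (median 0.61, or 0.39 to 0.98 with 1 library left out, adjusted p = 5.1e-05; adjusted p = 0.783 with an estimated correlation), with 0 of 16 genes changed in limma or edgeR, 5 in DESeq2, 6 at an unadjusted p under 0.05 and 4 adjusted over the list alone. For these 3 lists KO_secGAA 3 stood apart from the other treated mice, with list averages of 0.133, 0.009 and 0.123 against 0.869 and 0.961, 0.696 and 1.03, and 0.872 and 1.095. It lay within the WT_PBS range, whose highest averages were 0.146, 0.277 and 0.278, so the groups overlapped. The list of B and plasma cells was higher (median 2.42, or 1.54 to 4 with 1 library left out, adjusted p = 0.0425; adjusted p = 0.783 with an estimated correlation), with 0 of 6 genes changed in limma or edgeR, 2 in DESeq2, 3 at an unadjusted p under 0.05 and 2 adjusted over the list alone. Igkc, the kappa light chain of antibodies, lay at 189.5, 229.6 and 3.639 in the treated mice and 3.325, 1.159 and 0.4812 in WT_PBS. The list's call ended without WT_PBS 2, WT_PBS 3, KO_secGAA 1 or KO_secGAA 2 (adjusted p up to 0.174) and without scaling factors (adjusted p = 0.311).

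Slow fibre genes were higher as a list (median 1.99, or 1.05 to 2.91 with 1 library left out, adjusted p = 0.000277; adjusted p = 0.783 with an estimated correlation), with 0 of 10 changed in limma or edgeR, 1 in DESeq2, 7 at an unadjusted p under 0.05 and 1 adjusted over the list alone. The groups overlapped, with slow fibre averages of -1.614, 1.677 and -0.063 in WT_PBS and 2.1, 0.931 and 2.986 in KO_secGAA. Casq2 was at 17.37 ± 2.06 against 8.355 ± 2.30. The oxidative phosphorylation, TCA cycle and fast fibre lists were lower (medians -0.15, -0.18 and -0.16, adjusted p = 0.00011, 0.0137 and 0.0335; adjusted p = 0.783 for each with an estimated correlation). Their counts were 0 of 53, 0 of 18 and 0 of 14 in limma and in edgeR, 1, 0 and 2 in DESeq2, 3, 2 and 2 lower at an unadjusted p under 0.05 (and 1 TCA cycle gene higher), and 0 adjusted over the list alone. With 1 library left out, the medians were -0.31 to -0.04, -0.29 to -0.10 and -0.27 to -0.11. WT_PBS 1 was below every treated mouse for the first (-0.277 against -0.266, -0.05 and -0.166) and the second (-0.233 against -0.138, -0.114 and -0.088). The first call ended without WT_PBS 2 (adjusted p = 0.176), the second without WT_PBS 2 or WT_PBS 3 (adjusted p up to 0.22) and the third without WT_PBS 1, WT_PBS 3, KO_secGAA 1 or KO_secGAA 2 (adjusted p up to 0.0976). Without scaling factors, where the median of all genes was 0.155, these medians were 0.01, -0.02 and 0, and the TCA cycle list did not pass (adjusted p = 0.118). Tendon and cartilage markers were lower (median -0.35, or -0.70 to -0.27 with 1 library left out, adjusted p = 0.0445; adjusted p = 0.783 with an estimated correlation), with 0 of 7 changed in limma or edgeR, 1 in DESeq2, 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone. This ended without WT_PBS 2, WT_PBS 3 or any 1 of the KO_secGAA libraries (adjusted p up to 0.249). The groups overlapped, with a tendon and cartilage average of -0.551 in WT_PBS 1 against -0.392 and -0.519 in KO_secGAA 1 and KO_secGAA 2. The other 21 lists did not pass, at adjusted p from 0.0627 (immediate early genes) to 0.894 (autophagy). Without scaling factors the proton pump and proteasome lists passed as higher (adjusted p = 0.00425 and 0.00102) and erythroid markers as lower (adjusted p = 0.0413). Lysosomal genes had a median of 0.06 (0.03 to 0.14 with 1 library left out, adjusted p = 0.128), with 3 of 63 higher. Without WT_PBS 1 or KO_secGAA 3 the lysosomal list passed. Without scaling factors its median was 0.22 (adjusted p = 0.0982).

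In limma, 487 genes changed, 239 up and 248 down, 187 of them by at least 2-fold. The groups did not overlap for 26.9% of genes, where chance gives 10%. The count was 94 without WT_PBS 3, 143 without KO_secGAA 2, 181 without KO_secGAA 1 and 209 without WT_PBS 2. It was 983 with array weights, 1022 with DESeq2, 308 without the moderation trend and 1009 without scaling factors, of which 86.2% were up in place of 49.1%. With an estimated correlation 0 of 14 called lists (10 up, 4 down) held and 2 had an unadjusted p under 0.05, while fry called 2.

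The last comparison set the 2 knockout contrasts side by side, to ask which knockout differences the treatment took back. Of the 2867 genes changed by the knockout, 426 changed back with treatment: 271 rose and then fell, such as Mt3, Lgals3, Hexa and Ncam1, and 155 fell and then rose, such as Mstn, Phkg1 and Pfkfb1. The treated mean took back 52.9% of the knockout difference for Mt3, 74.7% for Lgals3, 67.1% for Hexa, 63.7% for Ncam1, 60.8% for Mstn and 80.1% for Pfkfb1 on the log2 scale. Less was taken back for Fetub (21.4%), Runx1 (22.5%), Trib3 (15.5%) and Itga4 (0.391%), none of them changed between KO_secGAA and KO_PBS. The former genes are examples that passed in that comparison and the latter are examples that did not. A gap between their shares follows from this choice, and no error was computed for the share of a single gene. Of the changed-back genes, 100 still differed from WT_PBS. Only 2 genes changed further in the direction of the knockout, Mpnd, lower, and 4933415F23Rik, higher, both chosen after their values were seen.

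Over all 2867 genes, the treated mean lay on the wild-type side of KO_PBS for 2710 (94.5%), and the median share taken back was 48.3%. Independent lists would give 33 genes that rose and then fell and 19.7 that fell and then rose. The 100 simulated sets of unchanged groups gave a mean of 0.02 genes and at most 1. Those groups held no knockout effect, so hardly any gene could pass in both contrasts, and they do not test the count of 426. The log2 fold changes of the 2 contrasts had a Pearson correlation of -0.677 across genes, where simulated unchanged groups gave -0.5, and a covariance of -0.160 against -0.031, a difference of -0.129. With 1 KO_PBS and 1 WT_PBS library left out of the calling, 81.2 to 91.7% of the genes had treated means on the wild-type side of the left-out KO_PBS library, and 39 to 51.4% of the summed difference between the 2 left-out libraries was taken back. The 3 KO_PBS libraries cannot be split into 2 sets of at least 2, so part of the excess of 426 over the independent lists may come from sharing them. The count was 153 to 275 without any 1 knockout library, 237 without WT_PBS 3, 266 without the moderation trend, 693 with DESeq2 and 898 without scaling factors (91% of them risen and then fallen, in place of 63.6%).

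**Figure D3:**
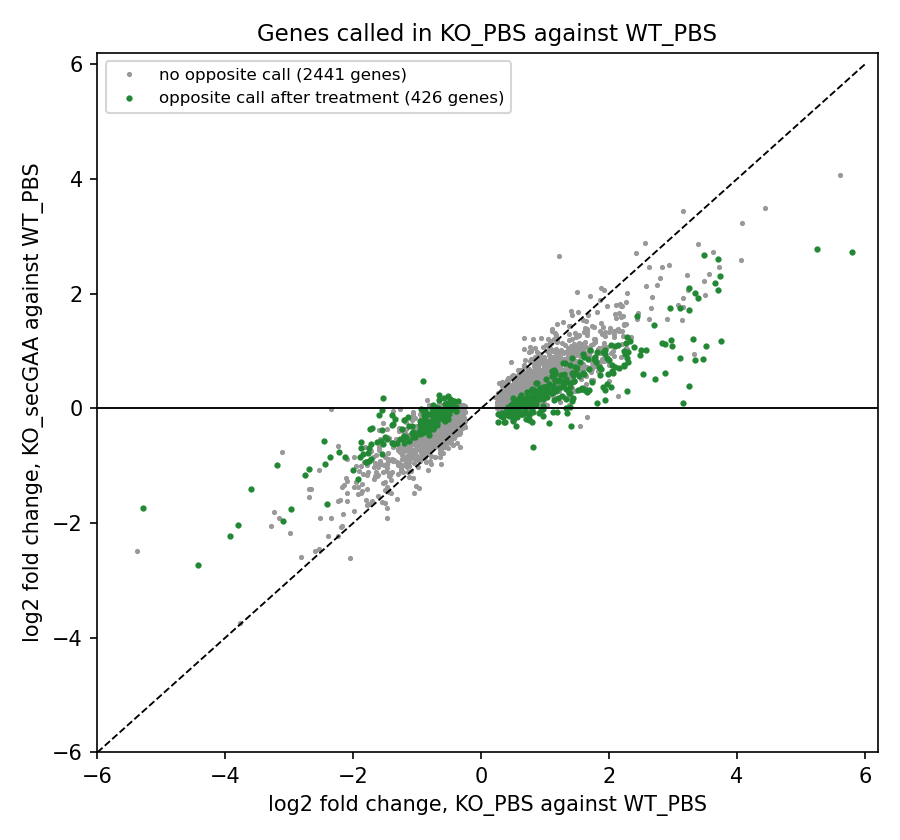
Log2 fold change of KO_secGAA against WT_PBS (vertical) over that of KO_PBS against WT_PBS (horizontal) for the 2867 genes changed by the knockout; green points are the 426 that changed back, and the dashed line marks equal values. Most genes lie between the dashed line and the horizontal line at 0.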

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

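Counts of changed genes depended on the scaling and on single libraries; unless the construction shows it, the cause was not tested. The 2867 genes of KO_PBS against WT_PBS became 4985 without scaling factors and 1784 at a minimum of 1.5-fold, and 1744 to 2847 with 1 library left out. The 481 of KO_secGAA against KO_PBS became 316 with the 2 compared groups only, 286 without the moderation trend, 798 with DESeq2 and 958 without scaling factors (159 to 568 with 1 library left out). The 487 of KO_secGAA against WT_PBS became 308 without the trend, 983 with array weights, 1022 with DESeq2 and 1009 without scaling factors (94 to 503 with 1 library left out). The 426 changed-back genes became 266 without the trend, 693 with DESeq2 and 898 without scaling factors (153 to 483 with 1 library left out). Called lists went from 21, 18 and 14 to 1, 0 and 0 with an estimated correlation and to 14, 6 and 2 with fry. Gaa in KO_secGAA against KO_PBS, at 0.04, was -0.112 without scaling factors and -0.025 to 0.141 with 1 library left out. Of named genes that had not passed, Kit in KO_PBS against WT_PBS turned to -0.034 with quantile normalization. With 1 library left out, signs turned in KO_PBS against WT_PBS for Tpsb2 (-0.123 to 0.74), Kit (-0.172 to 0.35) and Chad (-0.704 to 0.034). They also turned in KO_secGAA against KO_PBS for Cpa3 (-0.154 to 0.717), and in KO_secGAA against WT_PBS for Kit (-0.008 to 0.514) and Tpsb2 (-0.009 to 0.853). Of 98, 44 and 35 named changed genes in the 3 comparisons, 65, 26 and 14 passed in all 25 settings, and 0 reversed. Values without scaling factors, limma voom and thinned reads were chosen after seeing the data.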

Other observations

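The integrated stress response, whose target genes make and import amino acids, was not among the fixed lists. A list of 34 such genes was chosen after the values were seen, partly because Trib3, Asns and Fgf21 stood out, so what follows is a hypothesis. Of 33 tested, 16 rose in KO_PBS against WT_PBS and 0 changed between KO_secGAA and KO_PBS, while 7 were higher in KO_secGAA than in WT_PBS. Mthfd2, a mitochondrial folate enzyme, was at 7.24 ± 2.79, 48.9 ± 20.8 and 42.5 ± 14.8 in WT_PBS, KO_PBS and KO_secGAA, and Gdf15, a secreted stress signal, at 0.801 ± 0.391, 7.37 ± 2.69 and 5.57 ± 2.96. The transcript of Atf4, the transcription factor of this response, did not change (181 ± 10.9, 172 ± 27.4 and 207 ± 43.3). Its protein was not measured, so its activity cannot be read from this. Other listed genes did not pass in KO_PBS against WT_PBS either, such as Ddit3, Chac1 and Cebpb. Their log2 fold changes were 0.49, -0.01 and -0.1 (limma adjusted p = 0.21, 0.993 and 0.873). The 16 genes had on average 10.7% of the knockout difference taken back. Because genes picked for this pattern are among them, and such genes are regulated together, a comparison with random genes cannot test it.

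The tests of linkage to Gaa, of left-out libraries and of Ighm were chosen after the results were seen. The scaling factors of KO_PBS were above those of WT_PBS by 0.32 on the log2 scale (SE 0.04). Without the 50 most abundant genes the gap was 0.08 (SE 0.03), and at equal depth it was 0.32. A few abundant genes taking more of the WT_PBS reads would give such a gap. The 50 most abundant genes of each library did take more there, at 50.15 ± 0.564% of reads in WT_PBS, against 41.11 ± 0.404% in KO_PBS and 45.81 ± 0.769% in KO_secGAA. Thinning keeps each gene's expected share of the reads, so the value at equal depth could hardly differ and does not test depth.

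Of the genes changed by the knockout, 440 were changed in the same direction in KO_secGAA against WT_PBS, and 338 of them did not change between KO_secGAA and KO_PBS. Without Gaa, 13 of 439, or 2.96% (95% interval 1.59 to 5.01), lay within 20 Mb of it. That is 4.21% of its 309 tested neighbours, against 3.35% of all tested genes. Within 5 Mb it was 8 of 155 neighbours, or 5.16%. Most of these genes therefore do not lie near Gaa. With only 309 neighbours tested, most of the 439 could hardly have lain there. Effects of linked variants on distant genes would not show either, so the role of linked variants is open. The 338 had a median of 16% taken back (12.9 to 19.3) against 48.3% of all changed genes, but the planned bound was wrong, because these genes were chosen for staying away from WT_PBS. Simulated equal recovery gave 31 to 34.2% taken back but also 588 to 686 such genes against the 440 observed. It took the observed fold changes of the called genes as true, and choosing genes by their calls can overstate these. The simulation therefore cannot tell whether limited power accounts for these genes. Genes chosen on 6 libraries had a median of 27.8% taken back in the others, against 43.8% of all changed genes, over 27 combinations that reuse the same 9 libraries, with 7 to 445 genes each (-40.3 to 29.7% with KO_secGAA 1 left out, 19.2 to 47% with KO_secGAA 3), lower in 27 but under 0.5 of the share of all changed genes in only 10, so how much of the difference lasts is open.

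Ighm, the heavy chain of IgM, was at 402, 141 and 213 in WT_PBS, 14.3, 13 and 92.3 in KO_PBS and 316, 127 and 60.4 in KO_secGAA. B cells would also bring the light chain Igkc, but the highest Igkc to Ighm share in a WT_PBS library was 0.818%, in WT_PBS 1. The highest upper 95% limit, that of WT_PBS 2, was 1.3%, which covers counting error only. B or plasma cells are therefore not a likely source of Ighm in the wild-type mice, and where the reads come from is open.

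With 3 mice per group there are only 10 splits of 6 libraries, too few for a share under 0.05. The real split gave the largest gene count in 1 of 10 each time: 2655 against at most 7 for KO_PBS and WT_PBS, 316 against 9 for KO_secGAA and KO_PBS, and 354 against 2 for KO_secGAA and WT_PBS. For lists, splits with a count as large numbered 1 (21 against 18), 3 (18 against 21) and 4 (14 against 18). Of 100 drawn assignments of the 9 libraries, the real one included, 2 gave at least as many changed-back genes as the real 426. The other, at 440, is the same 3 groups with WT_PBS as the middle group. A further assignment, with WT_PBS as the middle group and the libraries of the 2 knockout groups mixed, gave 258. The rest gave at most 4.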
